A study of Mus musculus with 8 samples.

How the data were processed

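Total RNA was taken from round spermatids of BrdtΔBD1 mutant and control mice. The label protocols describe separation of the cells on a bovine serum albumin gradient between 2% and 4%, Trizol extraction with a column cleanup, and biotinylated cRNA made from 2 µg of RNA for Affymetrix arrays. Each of the 8 arrays received cells from 7 adult animals, 4 arrays per genotype, and the purity of the preparations was judged by propidium iodide staining, which the labels mention without a value. Groups and replicate numbers were taken from the sample titles. Every array had its own animals, so the p-values of the fits without a block rest on the spread between pools of animals together with any effect of the replicate number. The number of arrays limits the precision, and no sequencing depth applies to arrays.

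The deposited values are log2 intensities per probe set, normalized by the authors. The submitters' processing notes name GCRMA, a background correction that uses probe sequence together with quantile normalization and median polish, and limma. Their versions and the roles they had are not given in the sources used here. The log2 scale was checked from the values themselves, whose array medians lay between 3.10 and 3.14. Scanner files were not used here, so the background correction could not be varied. GCRMA compresses dim probe sets towards a floor, which makes fold changes of weakly expressed genes smaller than the change in RNA.

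The table holds 45101 probe sets. The 64 Affymetrix control probe sets were left out of all tests, which leaves 45037. Genes were named from the platform annotation, in which 34945 of the tested probe sets carry 1 gene, 932 carry several and 9160 are unnamed here. Symbols were updated by Entrez identifier through a gene table of the mouse assembly GRCm38.p6, in which 34741 of the single-gene probe sets were found. No build is named for the array files, so gene positions are not printed and only the chromosome is used. At gene level each of 18193 genes was represented by the single-gene probe set with the highest mean over all 8 arrays. Probe sets with several genes name no gene, so Gapdh and Ppia were not analysed here at gene level.

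Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, moderated variances, tests of both directions), with Benjamini-Hochberg adjustment and a threshold of 0.05, over probe sets and over genes. A gene is said to have risen or fallen when its adjusted p is under that threshold. Standard errors (SE) are those of the moderated model. Gene lists were tested with camera at its preset correlation of 0.01 and adjusted over 22 lists, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. List means per array were compared by an exact permutation test of both directions, whose smallest possible p for 4 against 4 arrays is 0.0286 when the pairing described below is left aside. Exact sign changes within the 4 pairs, a test chosen after seeing the data, cannot go below 0.125. Differences between probe sets of 1 gene were tested with diffSplice, by an F test per gene, over single-gene probe sets with a mean of at least 4 and genes with at least 2 of them. Chromosomes were compared by Fisher's exact test.

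The 22 lists were fixed before the data were examined. They are spermatid nuclear condensation, linker histones, core histones and variants, acrosome, flagellum and fibrous sheath, manchette and nuclear shaping, sperm energy metabolism, spermatid transcription regulators, BET proteins and elongation factors, heterochromatin and chromocentre, spliceosome, 3' end processing, piRNA pathway and chromatoid body, sex-linked spermatid genes, spermatocyte markers, spermatogonia markers, Sertoli cell markers, Leydig cell markers, peritubular, vascular and blood cell markers, stress, immediate-early and apoptosis, ubiquitin and histone removal, and ribosomal proteins. The rule for genes named in the text was fixed at the same time. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose mutant and control arrays do not overlap and whose higher group has a mean of at least 5. It leaves out symbols that are only clone or predicted names, of which 42 would have been eligible. It adds up to 4 members of each list with the smallest adjusted p among those past the threshold, the 6 genes with the smallest adjusted p in the test between probe sets, and a fixed set that holds Brdt, Brd2, Brd3, H1f6, protamines, transition proteins, Actb, Gapdh and Ppia, and of which a further member is not reported here. Where fewer than 3 genes passed in a direction, the 5 with the smallest unadjusted p would have been added, which was not needed. Further list members were named after their values were seen: Clu, Ctsl, Amhr2, Sox9, Amh, Stra8, Dmrt1, Sycp3, Gramd1b, Hspa8, Dhx8, Macroh2a1, Cyct, Slc25a31, Taf4b, Rfx3, Lmna, Uchl1, Cul4a and Rps4x, as well as further genes in the closing section.

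The labels give both groups the replicate numbers 1 to 4 without saying what a number marks. Deviations from the group means, over 11374 probe sets with a mean of at least 5, correlated between same-numbered arrays with r = 0.417, 0.508, 0.688 and 0.579 for numbers 1 to 4, while the highest r between different numbers was 0.144. Every array matched its own number best. The hybridization spike probe sets also went by number, with means of 12.30 and 12.26 on the arrays numbered 1, 8.52 and 8.39 for number 2, 7.94 and 8.14 for number 3, and 10.84 and 10.55 for number 4, mutant first. The numbers were therefore read as pairs, by this check of the values, and a fit with the replicate number as a block is given where it changes a result.

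The gene-level test was tested on simulated data with 18193 genes, of which some with a mean of at least 5 were changed by known amounts. It recovered 78.8% of genes changed by 2 on the log2 scale, 43.3% of those changed by 1 and 8.96% of those changed by 0.5, and 4.40% of its 91 calls were false. The test between probe sets recovered 74.2%, 23.9% and 1.49% at the same sizes over 2878 simulated genes, with 10.8% of 74 calls false. Both shifted lists of a simulated set were recovered with 0 false calls. The noise was drawn independently for each probe set, and the simulated lists were random genes. The simulation thus held no effect of the replicate number and no correlation between genes, both of which real arrays can have. Its rates, above all those of the list test, need not hold for the arrays used here. For the gene-level test, recovery of changed genes with a mean under 5 was not simulated.

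The alternatives set before the data were examined were the replicate block, leaving out each array in turn, shifting the array medians, quantile normalization of the deposited values, a trended and robust variance prior, array weights, leaving out probe sets that can match several transcripts, minimum means of 4 and 6, a fold limit of 2, no moderation of variances, and the mean of all probe sets of a gene. A Simes test was also run for the probe sets of a gene. Further alternatives were chosen after seeing the data: the mean of the Sertoli cell markers on each array (called the Sertoli score) as a covariate, the difference between the 3' and 5' Gapdh control probe sets as a covariate, and leaving out control arrays 1 and 3. The score ran from 5.55 to 7.07 on mutant arrays and from 4.61 to 5.45 on control arrays, without overlap. Differences at an equal score are therefore extrapolated from slopes within the groups, and score and genotype are largely confounded.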

Results

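Round spermatids are the haploid germ cells that follow meiosis and precede elongation and nuclear condensation. They were profiled in adult mice carrying the BrdtΔBD1 allele, in which the testis-specific chromatin reader Brdt lacks the first of its acetyl-lysine-binding bromodomains, and in control mice of the same 129 Sv/Ev strain. The comparison asks which transcripts of round spermatids differ when that domain is missing. There were 4 mutant and 4 control arrays, each from 7 animals of 2 to 4 months of age. Values of different arrays correlated with r between 0.970 and 0.994, and the first and second principal components held 39.5% and 25.7% of the variance. Control arrays 1 and 3 stood apart in RNA quality. Their 3' minus 5' difference of the Gapdh control probe sets was 1.68 and 2.05 on the log2 scale, against 0.46 to 0.48 on the other control arrays and 0.33 to 0.94 on the mutant arrays. Their 18S ribosomal RNA probe sets averaged 11.2 and 8.87, against 5.51 and 3.65 on the other controls and 8.11, 5.40, 5.03 and 3.99 on mutant arrays 1 to 4.

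The largest fall was that of Camk2n2, an inhibitor of calcium/calmodulin-dependent kinase II, from 7.76 ± 0.21 in control to 3.84 ± 0.35 in mutant arrays (SD, n = 4 each), a 15.1-fold lower level (adjusted p = 0.00016, limma). Next came Epyc, a small leucine-rich proteoglycan, 10.5-fold lower at 5.93 ± 0.30 against 9.32 ± 0.34, Fam20a, a pseudokinase of the secretory pathway (9.20-fold), and Ephx4, an epoxide hydrolase family member (8.57-fold). The largest rise was that of Fabp5, a fatty acid-binding protein, from 3.72 ± 0.84 to 7.73 ± 1.74, or 16.2-fold (adjusted p = 0.033). Glutathione transferases, enzymes that conjugate glutathione to electrophiles, made up 5 of the 12 largest rises: Gstm1 (15-fold), Mgst1 (12.7-fold), Gstm2 (12.3-fold), Gstp1 (9.04-fold) and Gstm7 (7.68-fold).

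The other large falls were those of Gtf2ird2, a TFII-I family member (7.33-fold lower, adjusted p = 0.00088), Smpdl3a, a sphingomyelinase-like phosphodiesterase (6.84-fold), Rpap3, a cochaperone associated with RNA polymerase II (6.68-fold), Ddit4l, an inhibitor of mTOR signalling (6.13-fold), and Elfn1, a leucine-rich transmembrane protein (5.86-fold). Rnpep, an aminopeptidase, fell by 2.52 (SE 0.28) on the log2 scale, Orai1, the pore subunit of the store-operated calcium channel, fell by 2.51 (SE 0.25), and Csrp2, a LIM-domain protein, fell by 2.40 (SE 0.23). Apart from Camk2n2, the adjusted p of the 12 largest falls lay between 0.00026 for Epyc, Smpdl3a and Elfn1 and 0.0061 for Rpap3. Among the rises, Nptx2, a neuronal pentraxin, was close to the floor in control at 2.43 ± 0.12 and reached 5.34 ± 0.43 in mutant arrays (7.50-fold, adjusted p = 0.00059). Col26a1, a collagen, rose 7.08-fold. Aard (8.30-fold), the defensin Defb19 (8.03-fold), the intermediate filament gene Vim (7.72-fold) and the cystatin Cst12 (7.37-fold) belong, like Fabp5, to the list of Sertoli cell markers. The mean of that list, the Sertoli score, was 1.47 higher (log2) in mutant than in control arrays, beside these rises. With it as a covariate the log2 difference of Fabp5 went from 4.01 (SE 0.80) to 0.60 (SE 0.51) and that of Col26a1 from 2.82 (SE 0.57) to 1.23 (SE 0.86). That of Nptx2 stayed at 2.78 (SE 0.39) from 2.91 (SE 0.21) and missed the threshold through its wider error, and 0 of the 12 rises passed. Fabp5, Aard, Defb19, Vim and Cst12 are part of the score itself, so smaller differences of these genes in that fit are partly built in. All differences at an equal score are extrapolated, as no mutant array scored as low as any control array. Of the falls Camk2n2 (adjusted p = 0.0046), Epyc, Smpdl3a, Ddit4l, Elfn1 and Csrp2 passed at an equal score. Apart from Camk2n2 they shared an adjusted p of 0.04996, just under the threshold, beside 0.0534 for Fam20a, which missed it. Fam20a (-3.20 to -3.10), Ephx4 (-3.10 to -3.18), Gtf2ird2 (-2.87 to -2.94), Orai1 (-2.51 to -2.66) and Rnpep (-2.52 to -2.72) stayed about as large and missed the threshold through wider errors, with SE of 0.23 to 0.28 before and 0.43 to 0.53 after. Rpap3 went from -2.74 (SE 0.35) to -1.75 (SE 0.53), with an adjusted p of 0.18. All 12 falls passed in each of the 8 fits that leave out 1 array (adjusted p up to 0.029, for Rpap3 without control array 4), as did the rises of Gstm1, Gstm2 and Nptx2. Without both control arrays 1 and 3, Rpap3, Rnpep, Csrp2, Gstm1 and Gstm2 missed the threshold, and Nptx2 was the 1 of the 12 rises that passed. Over 22 alternatives the adjusted p ran from 0.00073 to 0.18 for Rpap3, from 0.0014 to 0.077 for Rnpep and from 0.00069 to 0.053 for Csrp2. Vim missed the threshold without mutant array 3 alone, Gstp1 and Defb19 passed in 2 of the 8 fits, and Fabp5, Mgst1, Aard, Gstm7, Cst12 and Col26a1 passed in 1, the fit without mutant array 2, with adjusted p of up to 0.097, 0.088, 0.11, 0.080, 0.12 and 0.097 in the others. Those fits held no replicate block. In limma with the block and all arrays, the adjusted p of Fabp5, Mgst1, Aard, Gstm7 and Cst12 was 0.0074, 0.017, 0.020, 0.015 and 0.014.

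**Figure D1:**
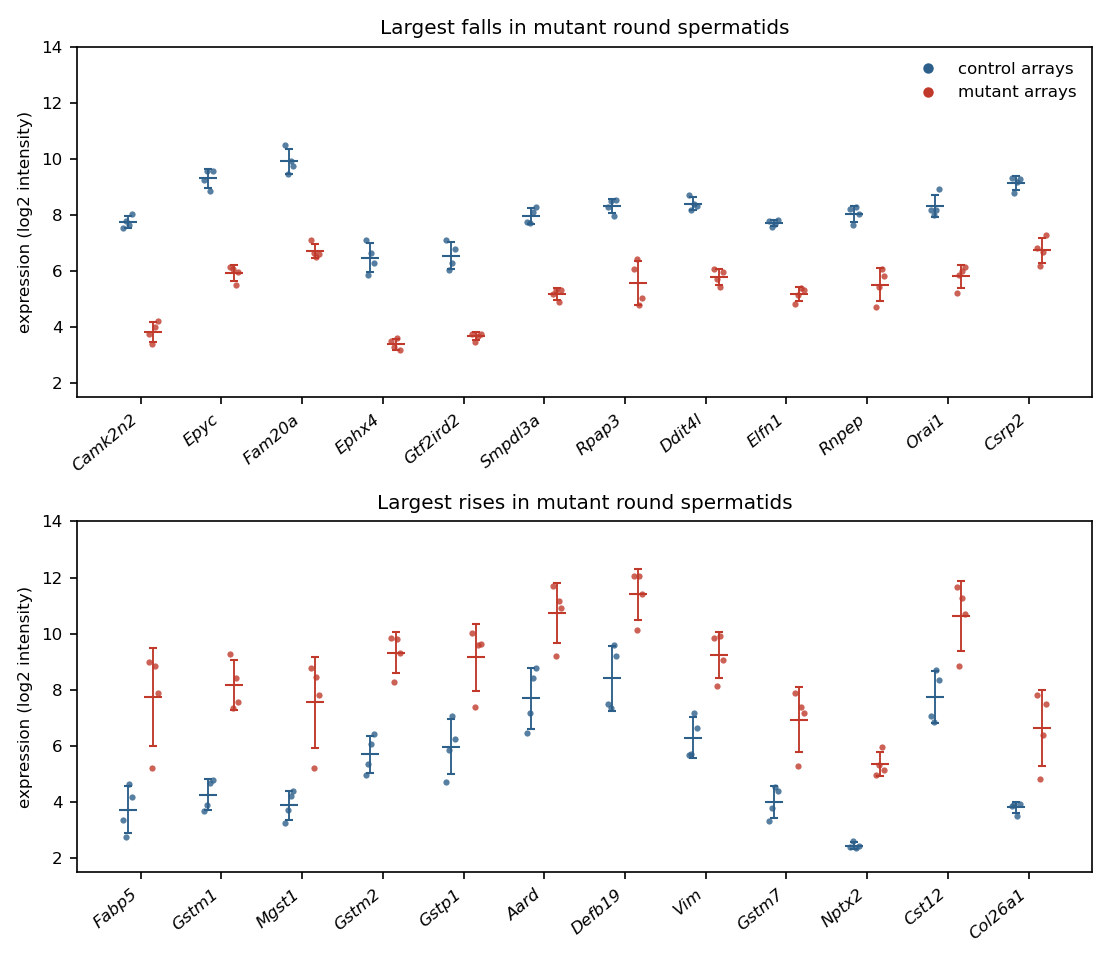
Expression (log2 intensity, vertical axis) of the 12 genes with the largest fall (top) and the 12 with the largest rise (bottom), with a point per array and bars for the mean ± SD of 4 control and 4 mutant arrays. The groups do not overlap for any of these genes, which was a condition of their choice, and the spread of Fabp5 in mutant arrays (SD 1.74) is wider than that of Camk2n2 (SD 0.35).

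Brdt itself was read by 3 probe sets. The brightest, 1435502_a_at, was 2.66-fold lower in mutant arrays (10.67 ± 0.33 against 12.08 ± 0.25, SD, n = 4; adjusted p = 0.0074 over genes). Over 22 alternatives its adjusted p ran from 0.0015 to 0.17, the highest with the Sertoli score as a covariate, where its log2 difference went from -1.41 (SE 0.19) to -1.24 (SE 0.36). Without control arrays 1 and 3 the difference of Brdt was -1.57 (adjusted p = 0.059). A further one, 1450178_at, was lower by 1.84-fold (adjusted p = 0.0495 over probe sets), and 1444667_at lay near the floor at 2.70 and 2.69. Where these probe sets lie relative to the deleted part is not known here, so they do not check the labels. The related BET genes Brd2 and Brd3 had log2 differences of -0.40 (SE 0.21, adjusted p = 0.33) and -0.56 (SE 0.18, adjusted p = 0.13). H1f6, the testis-specific linker histone, rose 1.55-fold at a low level, from 3.95 ± 0.23 to 4.58 ± 0.08 (adjusted p = 0.041 over genes). Over probe sets its adjusted p was 0.055, and 0.046 with the replicate block. It passed in 1 of 8 fits without 1 array, that without control array 4 (adjusted p = 0.030, and up to 0.11 in the others). Genes of the condensing spermatid nucleus were near the top of the intensity range in both groups. Log2 differences were 0.26 (SE 0.15) for Prm1, -0.06 (SE 0.13) for Prm2, 0.07 (SE 0.13) for Tnp1 and 0.16 (SE 0.13) for Tnp2, with adjusted p from 0.36 to 0.86. The difference of Actb was 0.20 (SE 0.18, adjusted p = 0.60). The signs of Prm2, Tnp1 and Actb turned under an alternative.

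In all, 339 genes rose and 336 fell among 18193 tested. The median rise was 1.24 and the median fall -1.18 on the log2 scale, with 237 rises and 214 falls of at least 2-fold, while the median over all genes was -0.02. Mutant and control arrays did not overlap for 670 of the 675 changed genes. Without overlap were 2298 of all genes, or 12.6%, where chance gives 2.86% when the pairing is left aside. Over probe sets, 323 rose and 316 fell among 45037. With the replicate number as a block, 1201 genes rose and 899 fell, which included 337 and 334 of the genes above, and 1767 probe sets rose and 1127 fell. Risen genes numbered 70 without mutant array 3, 755 without mutant array 2, 145 without mutant array 1 and 79 to 126 without 1 of the control arrays, and fallen genes numbered 129 without mutant array 3, 218 without mutant array 4 and 147, 152 and 139 without control arrays 1, 3 and 4. Without both control arrays 1 and 3, 18 genes rose and 50 fell, of which 16 and 46 were among the genes above, and with the Sertoli score as a covariate 8 rose and 13 fell, of which 4 and 13 were. Outside the 24 largest changes, Ints11 and Plekha3 are the genes named by the fixed rule that also passed without these 2 arrays. Neither Ints11 nor Plekha3 passed with the Sertoli score, where Plekha3 went from -1.73 (SE 0.20) to -2.04 (SE 0.36) and Ints11 from -1.49 (SE 0.13) to -1.28 (SE 0.23). The fall of Plekha3 is that of its brightest probe set. Another of its probe sets, 1420840_at, rose by 1.46 (adjusted p = 0.026 over probe sets, limma). With the mean of all its probe sets Plekha3 did not pass (adjusted p = 0.56).

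Markers of other testis cells were examined next, since the gradient could leave such cells among the spermatids. Sertoli cell markers were higher in mutant arrays: 6 of 24 measured rose, 16 when adjusted over the list alone and 14 with the replicate block, and 0 fell. Besides Fabp5, Defb19, Vim, Aard and Cst12, the tight junction gene Cldn11 rose 3.29-fold (adjusted p = 0.029; up to 0.090 when 1 array was left out). Its log2 difference was 0.55 (SE 0.38) with the list mean as a covariate, a mean that holds Cldn11 itself, so that part of the loss is built in. Clu, Ctsl and Amhr2 had log2 differences of 1.67 (SE 0.39), 2.00 (SE 0.47) and 1.65 (SE 0.60), with adjusted p of 0.052, 0.054 and 0.17. Amh lay near the floor, at 1.95 in mutant and 1.97 in control arrays, with a difference of -0.02. Sox9 read 3.80 in both groups, with a difference of 0.0048, a level no lower than the 3.72 from which Fabp5 rose. The list mean was 6.86, 5.55, 7.07 and 6.67 on mutant arrays 1 to 4 and 4.61, 4.83, 5.45 and 5.37 on control arrays 1 to 4. It was higher in the mutant array of all 4 pairs (exact permutation p = 0.0286 over all arrays, the smallest possible when the pairing is left aside, and 0.157 adjusted over 22 lists). In that permutation test 4 lists had an unadjusted p of 0.0286, those of Sertoli cells, spermatogonia, Leydig cells and stress, and 0 lists passed after adjustment. Exact sign changes within the 4 pairs gave p = 0.125, the smallest they allow, so the pairs alone cannot pass 0.05. Pairs of 1 sign were not particular to Sertoli markers. The spliceosome, spermatocyte and ribosomal protein means were also higher in all 4 pairs, and the acrosome and flagellum means lower in all 4. The Sertoli list passed the camera test (median log2 difference 1.5, adjusted p = 6.6e-09; adjusted p = 0.535 with an estimated correlation, the highest of its 15 alternatives, the lowest being 6.9e-14).

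Spermatogonia markers shifted the same way (adjusted p = 0.00092, median log2 difference 0.33; adjusted p = 0.53 with an estimated correlation, range over 16 alternatives 0.00018 to 0.75). Of 23 measured, 1 rose, also when adjusted over the list alone, and 6 with the block. The riser was Etv5, a transcription factor of spermatogonial self-renewal (2.44-fold, adjusted p = 0.042; past the threshold in 1 of 8 fits without 1 array, up to 0.11). With the Sertoli score as a covariate its log2 difference went from 1.28 (SE 0.28) to 0.29 (SE 0.32), with an adjusted p of 0.82 in a range over 21 alternatives of 0.0076 to 0.82. Stra8, the meiotic entry factor, and Dmrt1 had log2 differences of 1.53 and 1.38, past the threshold with the block (adjusted p = 0.015 and 0.034) and not without it (0.15 and 0.14). Of 37 spermatocyte markers 0 passed, over all genes or adjusted over the list alone, with 10 higher and 2 lower at an unadjusted p under 0.05. With the block 6 rose, among them Sycp3, a synaptonemal complex protein (log2 difference 0.99), and 1 fell. The camera test of that list gave an adjusted p of 0.062 (median 0.25), and 0.033 with the block, in a range over 16 alternatives of 0.00034 to 0.82. Leydig cell markers did not pass (adjusted p = 0.058). Of 16 measured 2 rose, Gsta2 (6.30-fold) and the retinaldehyde dehydrogenase Aldh1a1 (5.67-fold), and 2 rose and 1 fell, Gramd1b, adjusted over the list alone and with the block. Gsta2 passed in 1 and Aldh1a1 in 3 of the 8 fits without 1 array, with adjusted p up to 0.12 and 0.078. With the Sertoli score as a covariate the log2 difference of Gsta2 went from 2.65 (SE 0.60) to 0.09 (SE 0.35) and that of Aldh1a1 down to 0.89 (SE 0.57). Their adjusted p was then 0.96 and 0.63, in ranges over 21 alternatives of 0.0015 to 0.96 and 0.0049 to 0.63. Peritubular, vascular and blood cell markers were higher (adjusted p = 0.0175, median 0.25; adjusted p = 0.74 with an estimated correlation, range over 16 alternatives 0.0055 to 0.88; exact permutation p of the list mean 0.057, adjusted 0.180). In that list 1 of 28 rose, also adjusted over the list alone: Lum, a proteoglycan of connective tissue, at 3.91 against 2.85 (adjusted p up to 0.11 without 1 array). With the Sertoli score as a covariate its log2 difference went from 1.07 (SE 0.24) to 0.34 (SE 0.34), with an adjusted p of 0.79 in a range over 20 alternatives of 0.0136 to 0.79. Without control array 4 the adjusted p of the list was 0.053. The list mean was higher in the mutant array in 3 of the 4 pairs. In stress, immediate-early and apoptosis genes (adjusted p = 0.0067, median 0.13; adjusted p = 0.53 with an estimated correlation, range over 16 alternatives 0.0019 to 0.997), 1 of 29 rose, also adjusted over the list alone, and 4 with the block. It was Jun (1.71-fold, adjusted p = 0.030; up to 0.086 without 1 array), whose log2 difference went from 0.77 (SE 0.15) to 1.16 (SE 0.23) with the Sertoli score as a covariate and missed the threshold there with its wider error. The heat shock gene Hspa8 had a log2 difference of 1.11 (adjusted p = 0.14; 0.0095 with the block). Most genes of these lists read low. A control mean of at least 5 was reached by 5 of 23 spermatogonia, 3 of 16 Leydig, 4 of 28 peritubular and 8 of 29 stress genes. With a minimum mean of 4 the peritubular and stress lists did not pass. The Sertoli score was 1.47 higher in the same mutant arrays.

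**Figure D2:**
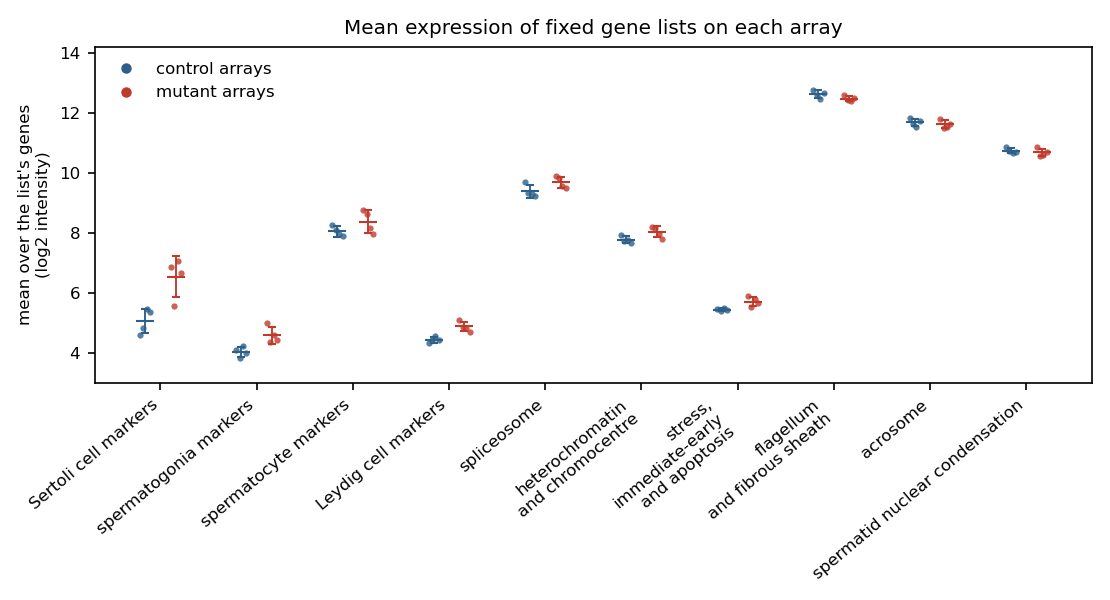
Mean log2 intensity over the genes of 10 fixed lists (vertical axis), with a point per array and bars for the mean ± SD of 4 control and 4 mutant arrays. Sertoli cell markers averaged 6.54 in mutant and 5.06 in control arrays, whereas the acrosome list averaged 11.62 and 11.68.

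Among genes of RNA processing, the spliceosome list was higher in mutant arrays (adjusted p = 0.0018, median log2 difference 0.19; adjusted p = 0.82 with an estimated correlation, range over 16 alternatives 2.2e-07 to 0.82; exact permutation p of the list mean 0.086, adjusted 0.236). Of 64 measured, 4 rose and 1 fell. Adjusted over the list alone 9 rose and 1 fell, and with the block 14 rose and 1 fell. The 3' splice site factor U2af1 rose 3.46-fold (9.77 ± 0.22 against 7.98 ± 0.39, SD, n = 4; adjusted p = 0.0037), the ribonucleoprotein genes Hnrnpa2b1 and Hnrnpm rose 2.80-fold and 2.01-fold, and the SR protein gene Srsf6 rose 2.35-fold. Dhx8, a helicase that releases spliced mRNA, fell 1.43-fold (adjusted p = 0.046). U2af1 and Hnrnpm passed in all 8 fits without 1 array, Srsf6 in 3 (adjusted p up to 0.079) and Hnrnpa2b1 in 2 (up to 0.11). In 3' end processing, 3 of 32 genes rose and 1 fell, 5 and 1 adjusted over the list alone and 6 and 2 with the block, and the list did not pass (adjusted p = 0.55). The risers were Ppp1ca, a phosphatase catalytic subunit (4.25-fold, adjusted p = 0.015), the poly(A) polymerase Papolg (3.51-fold) and the histone mRNA-binding protein gene Slbp (2.84-fold). Ints11, the endonuclease of the Integrator complex, fell 2.81-fold, from 9.15 ± 0.17 to 7.66 ± 0.16 (adjusted p = 0.0014), and passed in all 8 fits without 1 array. Ppp1ca passed in 6 (adjusted p up to 0.054), Slbp in 2 (up to 0.11) and Papolg in 1 (up to 0.12). Beside these changes, the mean of the spermatocyte markers was 0.33 higher (log2) in the mutant arrays, and its part in them was not tested. The Sertoli score was 1.47 higher in the same arrays. With it as a covariate none of these genes passed, while the spliceosome list had the lowest adjusted p of its alternatives, 2.2e-07. The log2 differences of Slbp, Hnrnpa2b1, Srsf6 and Hnrnpm were larger in that fit, at 2.39 (SE 0.46), 2.20 (SE 0.52), 1.73 (SE 0.37) and 1.28 (SE 0.27), with SE of 0.31, 0.31, 0.22 and 0.15 before, so wider errors ended the calls of the last 3. Slbp was no smaller relative to its error, and its call ended with the fewer degrees of freedom or the adjustment over genes. The difference of Ppp1ca went from 2.09 (SE 0.33) to 1.07 (SE 0.45), with an adjusted p of 0.37 in a range over 22 alternatives of 0.0027 to 0.37. That of U2af1 went from 1.79 (SE 0.20) to 1.61 (SE 0.38) and that of Papolg from 1.81 (SE 0.39) to 1.65 (SE 0.74).

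Of 28 genes of heterochromatin and the chromocentre, the cluster of pericentric heterochromatin in the spermatid nucleus, 2 rose and 1 fell, 6 and 1 adjusted over the list alone and 5 and 2 with the block (list adjusted p = 0.22). Lbr, the lamin B receptor, rose 4.12-fold (adjusted p = 0.033), the maintenance DNA methyltransferase Dnmt1 rose 2.17-fold and the methylation cofactor Dnmt3l fell 3.49-fold (adjusted p = 0.017). Of the 8 fits without 1 array, Dnmt3l passed in 5 (adjusted p up to 0.052), Lbr in 2 (up to 0.098) and Dnmt1 in 2 (up to 0.10). The Sertoli score was 1.47 higher in the same mutant arrays. With it as a covariate the log2 difference of Lbr went from 2.04 (SE 0.40) to 3.04 (SE 0.65) and that of Dnmt3l from -1.80 (SE 0.29) to -2.65 (SE 0.42), both short of the threshold. Lbr had the wider error relative to its difference, whereas Dnmt3l did not and fell short with the fewer degrees of freedom or the adjustment over genes. The difference of Dnmt1 went from 1.12 (SE 0.23) to 0.55 (SE 0.37), with an adjusted p of 0.64 in a range over 22 alternatives of 0.012 to 0.64. In the list of BET proteins and elongation factors, Brdt was the 1 of 16 genes that passed, and 5 were higher and 4 lower adjusted over the list alone, with 2 and 3 in the block (list adjusted p = 0.82). Of 7 linker histones 1 rose, H1f6, also adjusted over the list alone (list adjusted p = 0.27). Of 11 core histones and variants 0 passed, with 1 at an unadjusted p under 0.05. That was Macroh2a1, with a log2 difference of -1.26, which passed adjusted over the list alone and in the block (adjusted p = 0.029; list adjusted p = 0.80).

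Few genes of spermatid differentiation passed the test. In the flagellum and fibrous sheath list 1 of 38 genes fell, the testis-specific kinase gene Tssk4 (1.52-fold, adjusted p = 0.047), 2 adjusted over the list alone and 4 with the block, and the list shifted down (median -0.14, adjusted p = 0.0148; adjusted p = 0.82 with an estimated correlation, range over 16 alternatives 0.0015 to 0.82; exact permutation p of the list mean 0.114, adjusted 0.279). Its adjusted p was 0.064 without mutant array 3 and 0.053 without control array 4, and that of Tssk4 was up to 0.12 without 1 array. The Sertoli score was 1.47 higher in the same mutant arrays, and with it as a covariate the adjusted p of the flagellum list was 0.522, while the difference of Tssk4 went from -0.60 (SE 0.14) to -0.90 (SE 0.23), short of the threshold with its wider error. For the other spermatid lists 0 genes passed, over all genes or adjusted over the list alone, in limma. Higher and lower at an unadjusted p under 0.05 were 1 and 1 of 30 acrosome genes (list adjusted p = 0.22, median -0.10), 0 and 1 of 20 genes of nuclear condensation (0.89), 1 and 6 of 29 manchette genes (0.086) and 3 and 1 of 26 genes of sperm energy metabolism (0.80). They were 0 and 4 of 23 spermatid transcription regulators (0.22), 1 and 2 of 27 piRNA pathway genes (0.64), 1 and 0 of 16 measured sex-linked spermatid genes (0.22), 2 and 1 of 25 genes of ubiquitin and histone removal (0.27) and 1 and 0 of 32 ribosomal protein genes (0.22). The median of nuclear condensation genes was 0.0019 with a mean of -0.05 and a downward test. For sperm energy metabolism the median was -0.03 and the mean 0.0073 with a downward test, which turned upward after quantile normalization. With the block, 2 energy metabolism genes rose, the cytochrome gene Cyct and the carrier Slc25a31, as did 1 transcription regulator, Taf4b, 2 genes of the ubiquitin list, Uchl1 and Cul4a, and 1 ribosomal protein gene, Rps4x, whose log2 difference was 2.51 (SE 0.71, adjusted p = 0.089 without the block). The transcription regulator Rfx3 and the manchette list member Lmna fell with the block.

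Different parts of a transcript can be read by different probe sets of a gene, so probe sets of 1 gene with a mean of at least 4 were compared with each other to find transcripts whose parts changed unequally. In Plekha3, a phosphoinositide-binding protein gene, 1420839_at fell by 1.73 (SE 0.20) on the log2 scale and 1420840_at rose by 1.46 (SE 0.24), the 1 gene in which a probe set rose and another fell, each past the threshold. In Nol4l, 1457844_a_at fell by 1.91 (SE 0.28) while the 2 others differed by 0.61 and 0.57 (adjusted p = 0.10 and 0.24; 0.018 and 0.029 with the block). In Ddx5, an RNA helicase of the spliceosome list, 1423645_a_at rose by 1.83 (SE 0.28), from 6.67 to 8.50, while the brightest of its 6 probe sets, 1419653_a_at, read 14.36 in control and 14.44 in mutant arrays (adjusted p = 0.79).

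In Dcbld2, a transmembrane receptor gene, 1449891_a_at fell by 2.36 (SE 0.24) while the 1 other probe set tested, 1437635_at, differed by 0.39 (adjusted p = 0.28). In Zfand5, 1416083_at rose by 2.58 (SE 0.38), and the 3 others tested differed by 0.37 to 0.53, of which 1416085_s_at passed with the block (adjusted p = 0.038; 0.069 without it). In Ccdc30, 1430638_at fell by 1.70 (SE 0.26), and the 4 others tested differed by -0.69 to -0.01. Zfand5 and Ccdc30 have 7 probe sets each, of which 3 and 2 were too dim to be tested, as was 1 of 3 in both Plekha3 and Dcbld2. The adjusted p of these 6 genes in the test between probe sets lay between 0.00030 and 0.0024 (diffSplice in limma). Of 2870 genes with 6984 probe sets, 26 passed that test, 18 of them with probe sets of opposite sign, and 290 had an unadjusted p under 0.05. Of 36 spliceosome genes tested, 1 passed, Ddx5. With the replicate block 169 genes passed, all 26 among them, and without control arrays 1 and 3 the count was 2, and 1 with the Sertoli score as a covariate. Leaving out 1 array gave 10 to 36, with 10, 11, 11, 13, 14 and 10 without mutant arrays 1 and 3 and control arrays 1 to 4. Where each probe set lies in its transcript was not used here, and cross-hybridization to related genes was not tested. The Sertoli score was 1.47 higher in the mutant arrays in which these probe sets differed.

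**Figure D3:**
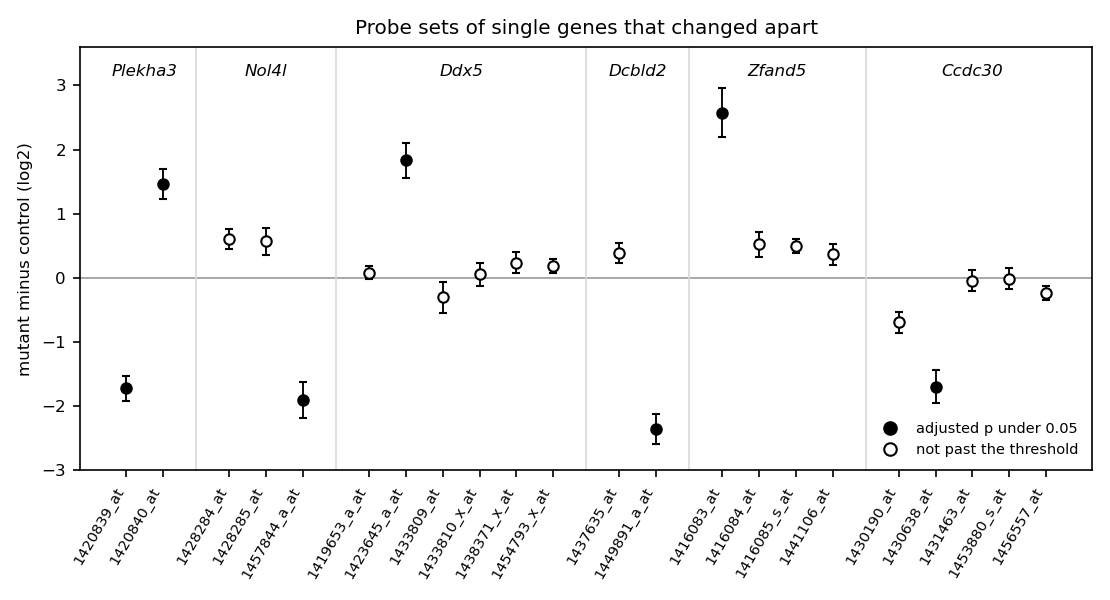
Difference between mutant and control arrays (log2, vertical axis; bars are SE, 4 arrays per group) for each tested probe set (mean of at least 4) of the 6 genes with the smallest adjusted p in the test between probe sets. Filled points passed the threshold over all probe sets; Plekha3 has a filled point on each side of 0, at -1.73 and 1.46.

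The sex chromosomes of round spermatids carry their own chromatin state, so changed genes were counted by chromosome. Risen and fallen genes were spread over the chromosomes of the mouse gene table without a chromosome passing the test. On X, 0.97% of 617 genes rose and 0.81% fell, against 1.90% and 1.87% elsewhere (Fisher's exact test, unadjusted p = 0.127 and 0.064). The 9 genes measured on Y were too few to tell. In 42 Fisher's exact tests, 1 for each chromosome and direction, 0 passed, the smallest adjusted p was 0.955 and 1 had an unadjusted p under 0.05, that of chromosome 7, on which 1.13% of 1413 genes rose against 1.93% elsewhere.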

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

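The tests of a lower share of round spermatids, of the 3' to 5' difference of control arrays 1 and 3 and of diluted spermatid RNA were chosen after the results were seen, as were the correlation of the Sertoli marker sets over the pairs, the Sertoli score as a covariate and the fit without control arrays 1 and 3. In 6 of 164 groups of 4 values, or 3.66%, 1 array lay far from the other 3, where chance gives about 5%. Tnp2 read 14.87 on mutant array 3, with the nearest mutant array at 15.10. Gstp1 read 7.39 on mutant array 2, with the nearest at 9.58. Dnmt3l read 6.08 on mutant array 2, with the nearest at 7.15. Ddx5 read 14.34 on mutant array 3, with the nearest at 14.47. The mean of the list of BET proteins and elongation factors was 8.82 on mutant array 1, with the nearest at 8.56. The mean of the list of ubiquitin and histone removal was 10.07 on mutant array 1, with the nearest at 9.56. Among 19 mouse control probe sets that entered no comparison, the 3' probe set of Gapdh was higher on every mutant than on every control array, with means of 11.31 and 10.75. Chance gives this to 1.43% of probe sets when the pairing is left aside.

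Sertoli cell markers were higher in the mutant arrays, by 1.47 in the list mean. The 3' to 5' difference of control arrays 1 and 3 is argued against as the whole cause, since the difference was 1.44 without those arrays, above the SD of 0.519 between arrays. More Sertoli cell RNA in the mutant preparations, which the albumin gradient should remove and the propidium iodide staining need not show, is a candidate explanation. The alternate members of the list, taken alphabetically as 2 sets, went together over the arrays with group means removed (r = 0.952). The exact one-sided permutation p was 0.0017, the smallest that 576 permutations within groups allow, with the pairing left aside. Over the 4 differences between same-numbered arrays r was 0.930 (exact one-sided permutation p = 0.042, the smallest they allow). The markers thus varied together, but with the group means removed this cannot tell what raised them in the mutant arrays. Of the 24 markers, 8 had a control mean of at least 5 and 0 belong to another list, and the 2 that read brightest in control arrays, Clu and Ctsl, went from 10.5 and 9.07 to 12.2 and 11.1, although readings of different probe sets do not rank RNA amounts. A lower share of round spermatids that raises every other cell type alike cannot be told apart from it, because all 5 spermatogonia markers compared already had a control mean of at least 5, although the medians of the 12 Sertoli and 5 spermatogonia markers, 2.64 and 1.38, differed by 1.26 (95% bootstrap interval 0.284 to 1.85), and higher Sertoli transcript levels as an effect of the genotype stay open, as untested.

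Of the genes that changed, 339 rose and 336 fell. A dilution shared by all spermatid transcripts is argued against as the whole source of the falls, because spermatid structural genes fell far less. The 72 of 117 acrosome, flagellum, manchette and nuclear condensation genes with a mean of 5 to 13, a range chosen after the results were seen, had a median log2 difference of -0.198 (quartiles -0.330 and -0.029). All 117 had a median of -0.105 (quartiles -0.272 and 0.040), against a median fall of -1.18 with an upper quartile of -0.869. The fallen genes were picked by adjusted p, which favours large falls, so their quartiles had to lie low. Whether the normalization held bright spermatid genes in place was not tested. Whether the rises come from Sertoli cell RNA cannot be told apart from an effect of the genotype: 333 risen genes outside the Sertoli list correlated with the Sertoli score with a median r of 0.265 (exact one-sided permutation p = 0.106, 207 positive), and 0.502 over the 4 differences between same-numbered arrays (exact permutation p = 0.125), too few arrays to decide. At an equal Sertoli score the median rise went from 1.23 (median SE 0.217) to 0.92 (0.350), and the median fall from -1.18 (0.190) to -1.14 (0.327), so that the calls of fallen genes ended mainly through wider errors and those of risen genes through smaller differences as well. No mutant array scored as low as any control array, so these differences are extrapolated and do not separate Sertoli cell RNA from genotype. With the pairing left aside, 1 of the 35 splits of the 8 arrays, the real one, gave as many genes (675, highest other 1) and 1 as many probe sets (639, highest other 16). The replicate numbers were read as pairs, however, so these splits are not interchangeable. The 8 splits that part all 4 pairs (highest others 0 and 0) are too few for a share under 0.05, so chance is not excluded for the counts.

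Probe sets of 1 gene changed apart in 26 genes. Sertoli cell RNA and a 3' to 5' difference between the arrays cannot be told apart from an effect of the genotype. The difference between the most risen and the most fallen probe set correlated with the Sertoli score with a median r of -0.210 (exact one-sided permutation p = 0.708), and 0.556 over the pairs (exact permutation p = 0.167), and with the Gapdh 3' minus 5' difference with -0.155 (exact permutation p = 0.198), and -0.370 over the pairs (exact permutation p = 0.333), which leaves both open with 8 arrays. Chance is not excluded, as 2 of the 35 splits gave as many genes, the real one included, and the highest other gave 166. That split sets arrays 1 and 3 of both groups against arrays 2 and 4 and keeps every pair together. Arrays 1 and 3 also had the higher 3' minus 5' differences, 0.60 to 2.05 against 0.33 to 0.59 for Gapdh and 1.54 to 2.43 against 0.97 to 1.39 for Actb. Replicate number and RNA quality thus cannot be told apart as the structure behind that split. With the number as a block the real count was 169.

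The count of called lists was 6, and chance is not excluded for it, as 15 of the 35 splits gave as many lists, with up to 13. Among the 8 splits that part all 4 pairs, the real one included and too few for a share under 0.05, the highest other counts were 10 lists and 0 genes with probe sets apart.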

How the results depend on the processing

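The Sertoli score and the 3' to 5' difference as covariates, and leaving out control arrays 1 and 3, were chosen after seeing the data. Of 1231 values of 57 named genes under alternatives, 926 kept direction and side of the threshold, 292 fell short of it, 7 newly passed and 6 turned sign, none of these in a gene past the threshold. With the block, 1201 genes rose and 899 fell, 1767 and 1127 probe sets did, 169 genes had probe sets apart, and spermatocyte markers had an adjusted p of 0.033. With array weights the counts were 980 and 675 genes, 804 and 535 probe sets and 151 genes with probe sets apart. Without moderation they were 34 and 69 genes and 8 and 24 probe sets. A trended robust prior gave 499 risen probe sets, and quantile normalization 618 fallen genes and 587 fallen probe sets, with flagellum at 0.059 and energy metabolism turned upward (0.765). A fold limit left 214 fallen genes. A mean of at least 4 gave 533 risen probe sets and 3 lists, with flagellum at 0.098, peritubular at 0.30 and stress at 0.33. Genes with probe sets apart numbered 13 with a mean of at least 6 and 383 with no filter, where dim probe sets lie near the floor. With the mean of all probe sets 10 lists passed, with Leydig at 0.0080, manchette 0.030, spermatocyte 0.044 and ubiquitin 0.025, while nuclear condensation turned upward (0.907) and Nol4l was at -0.24. An estimated correlation left 0 lists in camera (1 at an unadjusted p under 0.05), with 0.535 for Sertoli, spermatogonia and stress, 0.825 for flagellum and spliceosome and 0.745 for peritubular. In fry 0 passed (5 at an unadjusted p under 0.05), with 0.101 for Sertoli, spermatogonia and stress, 0.293 for flagellum, 0.258 for peritubular and 0.365 for spliceosome.

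With the Sertoli score, 8 genes rose and 13 fell, 0 and 2 probe sets did, 1 gene had probe sets apart, and Prm2 was at 0.11. List values were 0.522 for flagellum, 0.879 for peritubular, 0.75 for spermatogonia, 0.997 for stress, 0.047 for heterochromatin, 0.00010 for piRNA, 0.00034 for spermatocyte, and 0.997 and 0.577 for linker histones and energy metabolism, which turned sign. With the 3' to 5' difference there were 120 and 140 genes, 128 and 172 probe sets and 14 genes with probe sets apart. Without control arrays 1 and 3 there were 18 and 50 genes, 5 and 30 probe sets and 2 genes with probe sets apart, Actb was at -0.012, BET proteins turned upward (0.978), peritubular was at 0.072 and ribosomal proteins at 0.0080. Fewer arrays account for part of these losses and for those below, and the cause of the other changes was not tested.

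Leaving out each array in turn gave 70 to 755 risen and 129 to 376 fallen genes, 74 to 936 and 115 to 387 probe sets, 10 to 36 genes with probe sets apart and 4 to 9 lists. Adjusted p ranged from 6.9e-14 to 3.8e-06 for Sertoli, 0.00018 to 0.0046 for spermatogonia, 4.4e-06 to 0.022 for spliceosome and 0.0019 to 0.021 for stress. It ranged from 0.0015 to 0.064 for flagellum, 0.0055 to 0.053 for peritubular, 0.025 to 0.129 for Leydig, 0.0049 to 0.298 for spermatocyte, 0.022 to 0.918 for ribosomal proteins, 0.030 to 0.464 for acrosome and 0.029 to 0.203 for manchette. With turns of sign it ranged from 0.639 to 0.985 for nuclear condensation, 0.331 to 0.927 for core histones, 0.367 to 0.927 for energy metabolism, 0.684 to 0.955 for BET proteins and 0.237 to 0.90 for piRNA. Log2 differences ranged from -0.0098 to 0.12 for Tnp1 and from -0.15 to 0.0087 for Prm2. Shifted array medians, and leaving out probe sets that can match several transcripts, moved none of the counts of genes, probe sets or genes with probe sets apart by over 1.5 times. The Simes test, too, kept the count of genes with probe sets apart within 1.5 times.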

Other observations

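The glutathione transferases and the genes named here were chosen after their values were seen. Of 23 measured glutathione transferase genes, 7 rose and 1 fell. Besides Gstm1, Gstm2, Gstm7, Gstp1, Mgst1 and Gsta2, the riser was Gsta4 (6.34-fold, 7.60 against 4.93, adjusted p = 0.044), and Gstz1, an enzyme of tyrosine breakdown, fell 1.79-fold (adjusted p = 0.025). No test of the family is given, since it was picked for its rise. Gstm5, whose probe set read highest of the family, had a log2 difference of -0.08 at a mutant mean of 14.9. That is near the top of the intensity range, where a change may be hard to see. With the Sertoli score as a covariate, the differences of Gstm1 and Gstm2 were 2.43 (SE 0.55) and 1.88 (SE 0.29), adjusted p = 0.10 and 0.061, and those of Mgst1, Gstp1, Gstm7, Gsta2 and Gsta4 were 0.68, 0.52, 0.66, 0.09 and 0.15. Probes shared between these related genes were not tested here.

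In all 8 fits that leave out 1 array and in the fit with the replicate block, 55 genes rose and 111 fell. The fallen ones include all 12 of the largest falls, Brdt and Ints11, and further Dll3, a Notch ligand, and Dgat1, a triglyceride synthase. The risen ones include Gstm1, Gstm2, Nptx2, U2af1 and Hnrnpm, and further the transcription factor Yy1, the cell cycle kinase Cdk4 and the prion protein gene Prnp. Without both control arrays 1 and 3, 12 of the risen and 42 of the fallen ones passed. Ints11, Nptx2 and Prnp were among these, and Brdt, Dll3, Dgat1, Gstm1, Gstm2, U2af1, Hnrnpm, Yy1 and Cdk4 were not. With the Sertoli score as a covariate 17 of the changed genes passed, of which Camk2n2, Epyc, Csrp2, Smpdl3a, Elfn1 and Ddit4l were among the largest falls, and the risen ones were Prkra, Aurkb, 4930555G07Rik and R3hdm2. All of them but Camk2n2 (0.0046) shared an adjusted p of 0.04996, just under the threshold.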
